A study of Oryza sativa with 4 samples.

How the data were processed

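The series holds 4 shoot samples of rice, 1 for each combination of genotype (M202 or M202(Sub1)) and time under water (1 or 6 days). Per the labels' protocols, seedlings were grown in soil, RNA was extracted with Trizol, and biotin-labelled target was made by the manufacturer's in vitro transcription protocol for 1-colour Affymetrix arrays. Groups were taken from the genotype and time labels. The deposited table holds 1 log2 expression value per probe set and array, made by the authors with RMA, per the submitters' processing notes, and the version and the set of arrays normalized together are not given in the sources used here. RMA corrects background, forces the arrays to a common distribution and summarises the probes of a set, which compresses differences near background and hides any overall shift in RNA amount.

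The table has 57381 probe sets, of which 123 are controls, used only to check RNA quality and fungal signal. Of the 57258 rice probe sets, 22436 carry 1 gene symbol in the platform annotation used, 95 carry several and 34727 are unnamed here. The named ones stand for 17905 genes, all of which were matched by gene number to the RefSeq table of assembly ASM3414082v1, and 2451 of these have an informative symbol or synonym. That assembly was used only for names and for which genes neighbour each other. A gene with several probe sets was represented by the set with the highest mean over the arrays. Genes were kept if their highest value reached the 50th percentile of all values (5.51), which left 15426. Among genes at least 2-fold apart between genotypes and with several probe sets above the floor, all sets had the same sign in 88.9% of 36 at 1 day and 94.7% of 94 at 6 days.

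With 1 array per group, no test was made within a time or a genotype. Log2 differences are given as M202(Sub1) minus M202 and as 6 days minus 1 day, genes were counted at an absolute value of 1 or more, and no p-values are given for these counts. The median of each of 37 gene lists was placed among 10000 random lists of the same size drawn from 20 bins of mean level, and lists with under 4 measured genes got values only. A median at or under percentile 2.5 or at or over 97.5 was counted as outside. Between 9 and 14 of 34 lists lay outside in each of the 5 differences, where 1.7 would be expected for genes that vary independently. Genes of a list can move together on 1 array, so more can lie outside without any genotype or time effect. The lists were first written as 30 sets of description terms before the data were examined. The annotation used here carries symbols without descriptions, so the lists were rewritten as symbol patterns after the annotation had been seen and before any difference was computed. At that point 8 lists were added, among them chlorophyll synthesis and diterpenoid phytoalexins, and 1 was dropped. A secondary additive model (genotype plus time) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, Benjamini-Hochberg at 0.05) and leaves 1 residual degree of freedom, which is the interaction. "Rose" and "fell" are used for genes past this test. Its p-values weigh a mean difference against the interaction. They do not measure the spread between plants, harvests or arrays, since no group was replicated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.

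Named genes followed a rule fixed before the data were examined. For each of the 4 main differences it takes the 8 largest values in each direction among genes above the floor with an informative symbol and the same sign in all probe sets, the member of each list with the largest difference if at least 2-fold, and a set of core genes, of which 9 of 13 had a probe set. It also takes the 5 largest in each direction for the difference between time differences and 8 in each direction for genotype differences kept at both times. Genes named outside it are marked in the text. Names that give only a protein class, such as peroxidase, were not counted as informative, a choice made after some differences had been seen, which did not alter the lists. Known roles of genes are given as background.

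The calculations were tested on simulated data. Arrays were drawn around the real levels (standard deviation 0.25 for each gene, no interaction), with 100 genes changed by log2 1.5. The 2-fold rule counted 87% of them at 1 time, against 0.42% of 15226 unchanged genes. The limma test for genotype called 100% of them and 0.046% of the unchanged genes. On the real arrays the interaction is the residual of that model, so these limma rates do not carry over to them. The real spread is unknown with 1 array per group. The rates of the 2-fold rule thus hold only for the standard deviation chosen and are not error rates for the real counts. The alternatives tried were other level floors or none, the mean of all probe sets of a gene, leaving out probe sets whose names mark possible cross-hybridisation, quantile normalization or median centring of the deposited columns, a 4-fold threshold, eBayes without the trend or with robust settings, and a Benjamini-Hochberg threshold of 0.1. The planned count of genes around SUB1C was not run, and SUB1A, SUB1B, SUB1C and ADH1 are not reported here. A scan along all chromosomes, set up and run after seeing the data, took its place, and its window counts were set against 10000 random gene orders.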

Results

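Gene expression was measured in shoots of rice seedlings (Oryza sativa) kept completely under water. The plants were 18-day-old seedlings of M202, a japonica cultivar that tolerates submergence poorly, and of M202(Sub1), a near-isogenic line into which the Sub1 submergence tolerance locus has been introgressed. Shoots were sampled after 1 day or 6 days of submergence, which gives 4 groups with 1 Affymetrix rice genome array each. No group was replicated and no unsubmerged plants were compared, so the differences between single arrays are given without p-values, and the number of arrays limits their precision. The p-values printed come from an additive limma model over the 4 arrays. The median log2 signal was 5.53 for M202 and 5.53 for M202(Sub1) at 1 day, and 5.48 and 5.51 at 6 days. Of 17905 genes with a probe set, 15426 lay above the level floor, a log2 signal of 5.51 on at least 1 array. A value under the floor on some array is near background, so the size and rank of a difference that uses it are uncertain. SUB1A, SUB1B, SUB1C and ADH1 were not analysed here.

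The first comparison asked how the genotypes differed after 1 day under water. Of 4 genes of ethanol fermentation, 3 were higher on the M202(Sub1) array. PDC1, a pyruvate decarboxylase, stood at 11.55 against 8.92 in M202, a log2 difference of 2.63, and the alcohol dehydrogenase gene Adh2 was higher by 1.60 and PDC2 by 0.72. The median of the 4 measured fermentation genes was 1.16, a 2.24-fold difference at percentile 100 of 10000 random lists matched on level. 2 of the 4 genes were at least 2-fold higher, and PDC3, named after its values were seen, lay at -0.31. Also higher were the nonsymbiotic hemoglobin gene NSHB2 (2.54), the pyruvate orthophosphate dikinase PPDK2 (2.97), the heat shock factor HSFA3 (2.06), the small heat shock protein HSP26.7 (2.71) and the gibberellin 20-oxidase GA20OX2 (1.06). The 17 glycolysis genes had a median of 0.15 (percentile 99.7), which came to 0.10 (percentile 95.7) without probe sets whose names mark possible cross-hybridisation, and PIP2-5, an aquaporin, was higher by 1.81.

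Chlorophyll breakdown genes were lower in M202(Sub1) at 1 day. All 4 measured members lay below 0 with a median of -0.97 at percentile 0, and SGR, the stay-green gene that starts chlorophyll degradation, was at 8.28 against 9.83, a difference of -1.55. Cellulose synthesis and lignin genes had a median of -0.30, with 24 of 27 members below 0 and 4 at least 2-fold lower, among them the laccase LAC20 (-1.74) and the 4-coumarate:CoA ligase gene 4CL2 (-1.62). Of 22 expansins and xyloglucan enzymes, which loosen cell walls, 20 lay below 0 (median -0.24), although none was 2-fold apart. The isocitrate lyase gene ICL of the glyoxylate cycle (-2.63), the calmodulin-like genes CML31 (-2.03) and CML15 (-1.74), the homeobox gene OSH1 (-2.35, and -3.56 without possibly cross-hybridising probe sets) and the cold-responsive regulator DREB1B (-1.19) were lower as well. Diterpenoid phytoalexin genes, which make antimicrobial compounds, were higher at this time (median 0.43, percentile 100), a list written after the annotation was seen and before any difference was computed. CPS2, a copalyl diphosphate synthase, was at 5.48 against 3.48, and the P450 gene CYP76M7 was at 5.30 against 5.06. These values all lay under the floor, so the list median rests in part on signal near background. The pathogenesis-related gene PBZ1 was higher by 2.25. The DELLA growth repressor gene SLR1 (0.16), SLRL1 (-0.17), the sucrose synthase SUS1 (-0.07), the ACC oxidase ACO1 (-0.24) and the alpha-amylase AMY3D (-0.39) were less than 2-fold apart. Among all genes, 120 were at least 2-fold higher and 156 at least 2-fold lower in M202(Sub1), together 1.79% of the genes. At 4-fold the balance was the other way, with 28 higher and 19 lower.

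The same comparison after 6 days gave more genes apart. Cell division genes were higher in M202(Sub1). The 28 cell cycle and histone genes had a median of 0.85 (percentile 100), with 13 at least 2-fold higher, 25 above 0 and none 2-fold lower. The D-type cyclin CYCD2-2 was at 7.85 against 5.28. Ribosomal protein genes were higher by a small amount, with 22 of 23 above 0 and a median of 0.29. The same 3 fermentation genes were higher (median 1.24), with PDC1 at 8.21 against 4.86 and Adh2 higher by 1.52. HSP26.7 was at 10.33 against 4.42, the latter under the floor, and PPDK2 (3.53) and HSFA3 (3.50) were also higher. The jasmonate response repressor JAZ13 was higher by 2.77, the abscisic acid 8'-hydroxylase ABA8OX1 by 2.71, the trehalose phosphatase OsTPP1 by 2.44 and DREB1G by 2.55. ACO1 (0.59), SLR1 (0.31), SLRL1 (0.23), SUS1 (0.14) and AMY3D (-0.16) were less than 2-fold apart. Among all genes, 594 were at least 2-fold higher and 336 lower in M202(Sub1), together 6.03% of the genes.

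Defence genes were lower in M202(Sub1) than in M202 at 6 days. All 10 measured diterpenoid phytoalexin genes lay below 0, with a median of -1.29 (2.44-fold, percentile 0), and 6 were at least 2-fold lower. CPS2 was at 6.11 against 8.23, and the P450 genes CYP76M7 and CYP71Z7 differed by -2.38 and -2.21. Of 13 defence genes, mostly chitinases, 12 lay below 0 and 5 were at least 2-fold lower (median -0.90, percentile 0), among them PBZ1 at -1.94. The germin-like genes GER2 (-3.27) and GER3 (-2.34), the nicotianamine synthase NAS1 (-2.63) and the metallothionein gene MT1B (-2.20) were also lower. Chlorophyll breakdown genes remained below 0 in all 4 cases (median -0.77), with SGR at -0.90. Every 6-day genotype difference rests on the same M202 array as the time difference in M202, so these values are not independent.

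**Figure D1:**
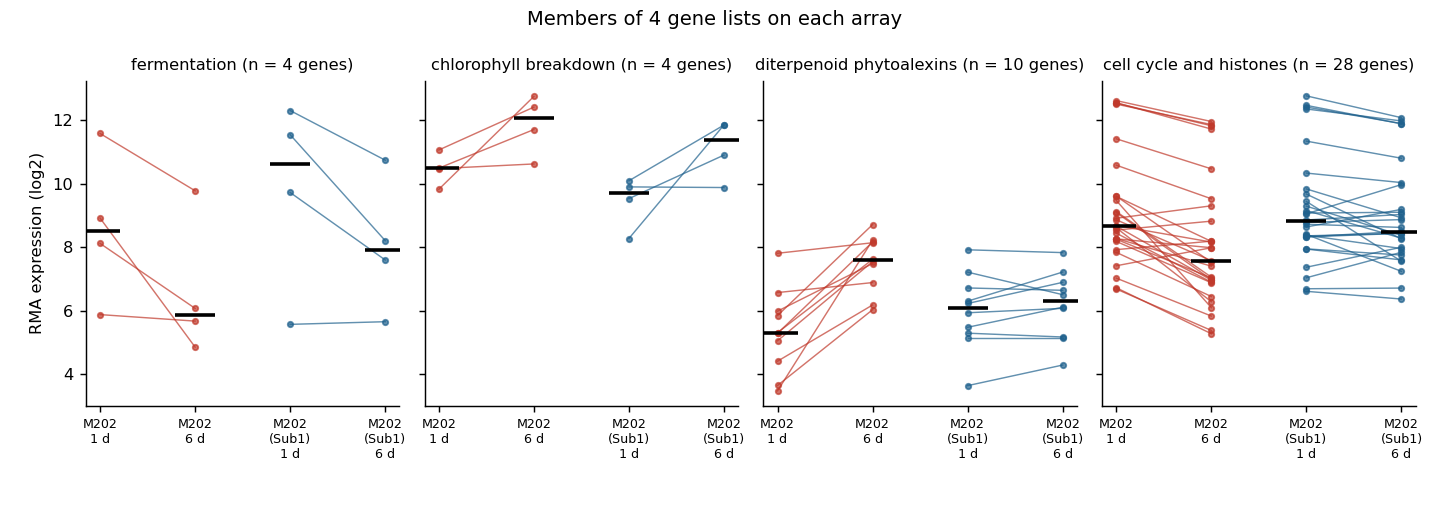
Each line is 1 gene and joins its RMA log2 expression at 1 day and 6 days of submergence in M202 (red) and M202(Sub1) (blue), and black bars are list medians on each array. All 10 diterpenoid phytoalexin genes were lower in M202(Sub1) than in M202 at 6 days, while the median of the 28 cell cycle and histone genes was higher by 0.85.

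The next question was which genotype differences were seen at both times, since the 1-day and 6-day differences share no array. Across genes, which are not independent replicates, they correlated with Pearson's r = 0.396 and Spearman's rho = 0.308. 67 genes were at least 2-fold higher in M202(Sub1) at both times, where 4.62 would be shared by independent lists of that size, and 49 were at least 2-fold lower, against 3.40. Of the 120 genes that were 2-fold higher at 1 day, 81.7% were above 0 at 6 days, and of the 156 lower genes 71.8% stayed below 0. In the other direction, 64.0% of the 594 genes 2-fold higher at 6 days were above 0 at 1 day. Of the 336 lower at 6 days, 82.7% were below 0 at 1 day. The named genes with the largest positive differences kept at both times were PPDK2, HSP26.7, PDC1, HSFA3, NSHB2, PIP2-5, SMR1 (1.82 and 2.32) and IAA20 (LOC4340245, 1.60 and 2.26), an auxin response repressor. Among these, HSP26.7 and IAA20 were under the floor on both M202 arrays, and PDC1 and NSHB2 on the M202 6-day array. PPDK2 rests on 1 probe set, whose name marks possible cross-hybridisation. Named genes lower at both times, not all by 2-fold, included MT1B (-1.60 and -2.20), the chitinase Cht10 (-1.04 and -1.06), the homeobox gene HOS66 (-1.03 and -1.28), RH2 (-1.12 and -2.85), the ABC transporter ABCG48 (-0.98 and -2.41), SGR (-1.55 and -0.90) and the dehydrin RAB21 (-0.89 and -1.38).

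The genes kept at both times were not spread evenly along the chromosomes. Gene order was taken from the rice RefSeq assembly ASM3414082v1, and the scan was set up after the data had been seen, because the planned count around SUB1C was not run. Chromosome 6 held 22 of the 116 kept genes, or 1.83% of its 1202 measured genes, and chromosome 3 also held 22, or 1.01% of 2185, with at most 5 in a window. On chromosome 6, 13 fell in 1 window of 101 neighbouring measured genes, where 0.76 would be expected. The highest count in any window of 10000 random gene orders was 8. Random orders treat neighbouring genes as independent, so neighbours that vary together can exceed such counts. Of the 13 genes, 10 were lower and 3 were higher in M202(Sub1). LOC4339944 was at 10.70 and 7.81 on the M202 arrays and at 3.93 and 3.30 on the M202(Sub1) arrays, LOC4339940 differed by -5.97 and -5.52, and LOC4339947 differed by 2.56 and 3.33 in the other direction. These 3 genes were picked after their values were seen. On chromosome 9, which carries Sub1, 3 of 831 measured genes were kept at both times, with at most 1 in a window. Their positions relative to Sub1 were not examined, so this count does not describe the region around Sub1. LOC4344943 on chromosome 8, also picked after its values were seen, was at 12.20 and 10.35 on the M202(Sub1) arrays at 1 and 6 days and under the floor on both M202 arrays.

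**Figure D2:**
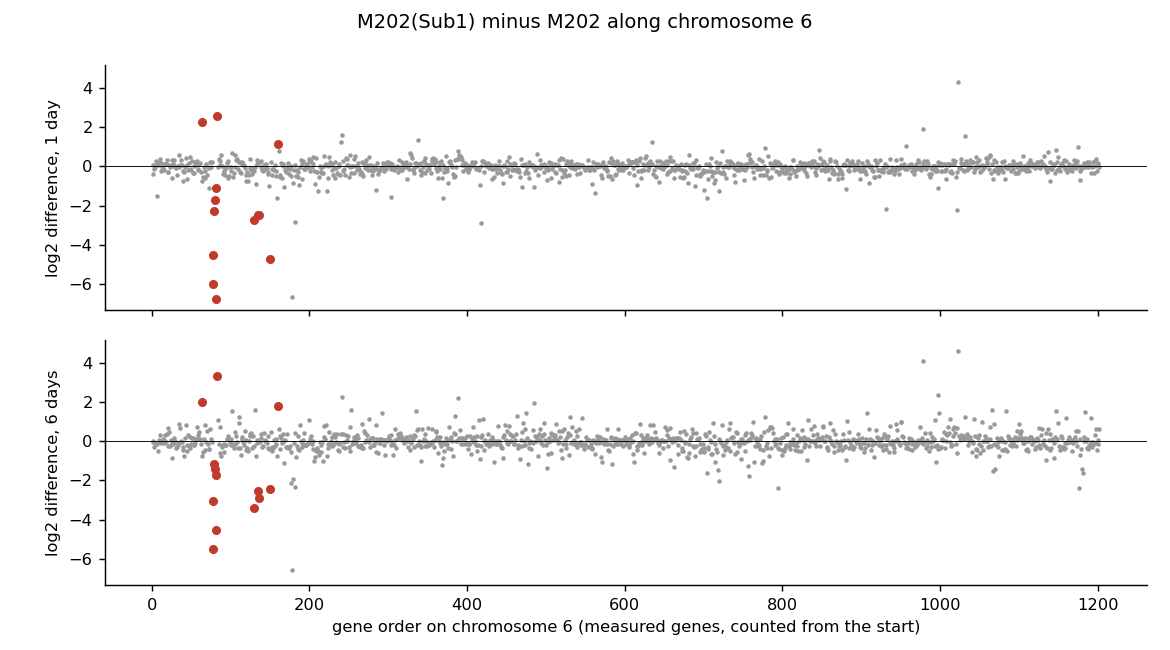
Log2 difference of M202(Sub1) minus M202 at 1 day (top) and 6 days (bottom) for each measured gene on chromosome 6, in gene order. Red points are the 13 genes of the densest window with a difference of at least 2-fold in the same direction at both times, of which 10 lie below 0 and 3 above.

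**Figure D3:**
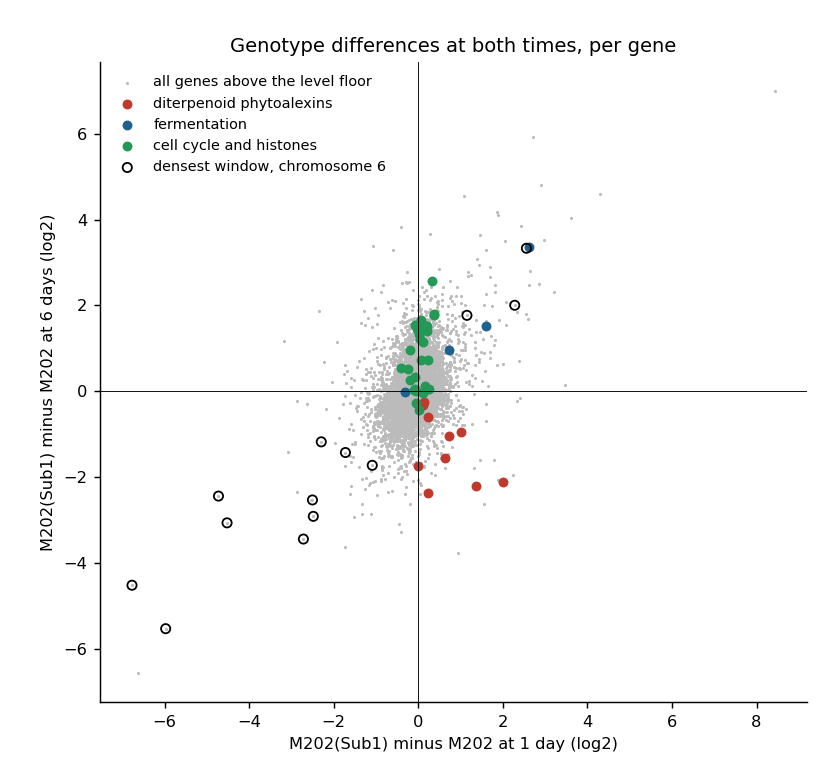
Each point is 1 of 15426 genes, with its log2 genotype difference at 1 day on the x axis and at 6 days on the y axis. Fermentation genes lie above 0 at both times apart from PDC3, phytoalexin genes lie below 0 at 6 days, and open circles mark the 13 chromosome 6 genes.

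An additive limma model over the 4 arrays, with 1 residual degree of freedom that holds the interaction, called 1 gene for genotype at a Benjamini-Hochberg adjusted p of 0.05. This was LOC4340120 on chromosome 6, lower in M202(Sub1) by a log2 value of -6.59 (adjusted p = 0.0315, limma), with lower values at both times. It lay under the floor on both M202(Sub1) arrays, at 4.98 and 5.25. No sequence was used here, so a poor match to its probes cannot be told apart from lower expression. The count ranged from 0 to 11 genes over the alternative settings, and 1669 genes had an unadjusted p under 0.05.

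The time comparison asked how shoots differed between 6 days and 1 day of submergence. Anything else that differed between the 2 harvests, such as plant age or hour of day, cannot be told apart from time under water. Among the circadian clock genes, LHY rose by 1.25 and GI, picked after its values were seen, fell by 1.03. The median of that list was -0.25 in M202 and -0.35 in M202(Sub1), inside the random range. Of the 4 fermentation genes, 3 fell with time, also when adjusted over the list alone. PDC1 fell by 3.70 on the log2 scale over both genotypes, Adh2 fell by 2.09 and PDC2 fell by 1.68, each lower at 6 days in both genotypes (adjusted p = 0.0145 for each, limma). NSHB2 fell by 3.02. NSHB1 fell by 1.96, but its difference in M202(Sub1) came to -0.03 without possibly cross-hybridising probe sets. SUS1 fell by 1.13, and the invertase CIN2 fell by 2.11. The alpha-amylase AMY3D rose by 2.40 (adjusted p = 0.0156, limma), although its 2 probe sets differed in sign in each genotype and their mean gave 1.06 in M202 and 1.20 in M202(Sub1). The AMY3D probe set with differences below 0 lay under the floor on each array, with values from 3.55 to 3.88. The hexokinase HXK6 rose by 2.75 and the glutamate dehydrogenase GDH2 by 2.49.

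Of 15 chlorophyll synthesis genes, a list written after the annotation was seen, 11 fell and the other 4 did not pass the test (12 fell when adjusted over the list alone), and each of the 15 was below 0 in both genotypes. PORA, a protochlorophyllide oxidoreductase, fell by 2.85 (adjusted p = 0.012, limma), with a lower value at 6 days in both genotypes. Of the 4 chlorophyll breakdown genes 3 rose, also when adjusted over the list alone, and SGR rose by 3.25 (adjusted p = 0.0137, limma), with higher values at 6 days in both genotypes. The list medians were 1.28 in M202 and 1.56 in M202(Sub1). Of 12 photosynthesis genes 4 fell and none rose (8 fell when adjusted over the list alone), and the chlorophyll a/b-binding protein gene RCABP69 fell by 1.24.

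Among regulators and stress genes, 5 of the 6 WRKY transcription factors on that list rose (5 adjusted over the list alone). The list holds only genes whose symbol matched, so other members of the family may be missing. Its medians were 1.87 in M202 and 1.84 in M202(Sub1). WRKY24 rose by 2.54 and WRKY62 by 2.07. The calmodulin-like genes CML31 and CML15 rose by 5.42 and 4.75 (adjusted p = 0.0207 and 0.0258, limma), and were higher at 6 days in both genotypes. ACS2, an ACC synthase of ethylene production, rose by 2.82 and ICL by 3.65. Of 30 jasmonate genes 7 rose and 1 fell (11 and 2 adjusted over the list alone), with the lipoxygenase CM-LOX2 up by 3.39. Of 39 heat shock genes 7 rose and 3 fell (9 and 3 adjusted over the list alone). Aquaporin genes fell where they passed the test, 5 of 21 with none up, and PIP2-7 fell by 4.78 (adjusted p = 0.0136, limma; 5 of 21 also adjusted over the list alone). Of 23 ribosomal protein genes 6 fell, or 16 when adjusted over the list alone. JAZ13 was higher at 6 days by 2.10 in M202 and 5.13 in M202(Sub1) and DREB1B by 2.04 in M202 and 4.93 in M202(Sub1), but neither passed the test.

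In M202, 1147 genes were at least 2-fold higher and 1330 lower at 6 days, and in M202(Sub1) 964 were higher and 711 lower. The time differences of the genotypes, which share no array, correlated across genes with r = 0.796, and 745 genes were at least 2-fold higher in both and 478 lower in both. Independent lists would share 71.7 and 61.3. In M202 the balance depended on the setting, with 46.3% of the 2-fold genes higher as deposited, 50.9% after centring each array on its median and 64.4% among genes at least 4-fold apart. The additive model called 2868 genes for time, 1472 up and 1396 down, and 1428 genes when the variance trend was left out of the moderation. With quantile normalization, or at an adjusted threshold of 0.1, more genes were called down than up. The other settings kept more up than down.

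**Figure D4:**
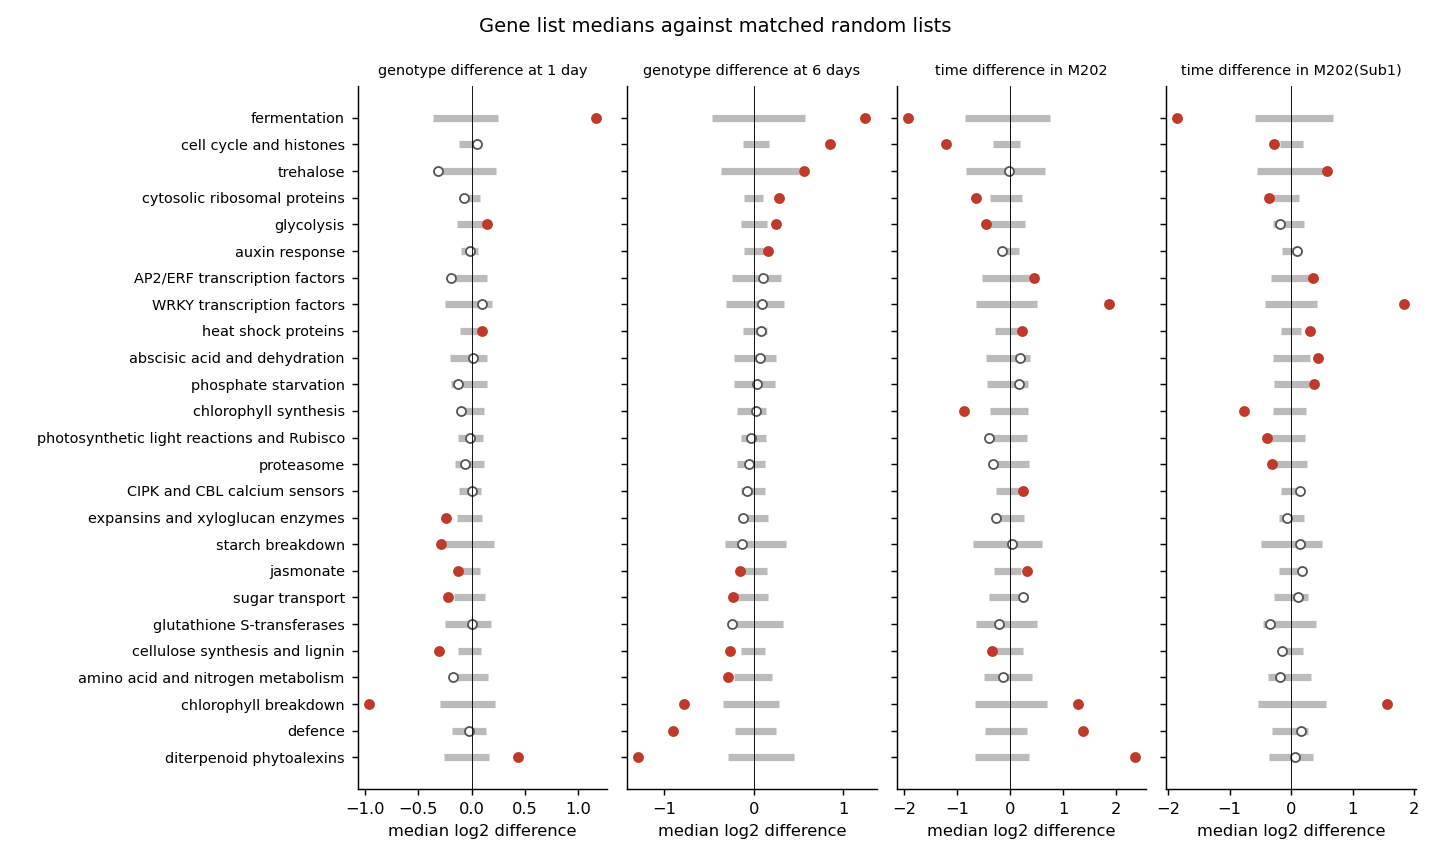
Points are the median log2 differences of the gene lists with at least 4 measured genes whose median lay outside the central 95% of 10000 random lists, matched on level, in at least 1 difference. Grey bars show that central range and red points lie outside it. Diterpenoid phytoalexin genes reached 2.35 for time in M202 and 0.07 in M202(Sub1).

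The last comparison asked where the time difference itself differed between the genotypes, which was not tested. Diterpenoid phytoalexin genes were higher at 6 days than at 1 day in M202, with a median of 2.35 and 8 of 10 at least 2-fold higher, and had a median of 0.07 in M202(Sub1). The median difference between these time differences was -1.87 (percentile 0), with all 10 members below 0. CPS2 went from 3.48 to 8.23 in M202 and from 5.48 to 6.11 in M202(Sub1). Defence genes had medians of 1.36 and 0.16, and PBZ1 went from 9.26 to 12.31 in M202 and from 11.51 to 10.37 in M202(Sub1). No phytoalexin gene passed the additive time test. That test takes the interaction as its residual, so genes apart in 1 genotype only can hardly pass it, and this outcome does not bear on M202 alone. Cell cycle and histone genes were lower at 6 days, more so in M202, with a median of -1.21 and 16 of 28 at least 2-fold lower there against -0.27 and 3 in M202(Sub1). The mitotic cyclin gene CYCB2 (LOC4342121) differed by -3.38 and -1.88. In the additive test 8 of the 28 fell and none rose (11 and 1 adjusted over the list alone). Chlorophyll synthesis genes also had a difference between time differences of 0.30, and ribosomal protein genes of 0.35. There were 648 genes with a time difference at least 2-fold higher in M202(Sub1) than in M202 and 246 lower. Named genes with high values included OSH1 (4.23, and 6.48 without possibly cross-hybridising probe sets), HSP26.7 (3.20), JAZ13 (3.03), DREB1B (2.89) and OsPP2C30 (2.80). Those with low values included PBZ1 (-4.19), NAS1 (-4.18), CPS2 (-4.11), CYP71Z7 (-3.57) and GER2 (-2.86). Of these, OSH1, HSP26.7, JAZ13, OsPP2C30, NAS1 and CPS2 were under the floor on some arrays. The genotype, time and interaction effects of the 4 arrays, set on the same scale, had standard deviations across genes of 0.374, 0.745 and 0.254.

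Controls for RNA quality and other tissues were compared between the arrays. The 3' minus 5' log2 difference of the actin control ran from 2.26 to 2.52 over the arrays and that of GAPDH from 0.60 to 0.81, both highest on the M202(Sub1) 6-day array. That of cyclophilin ran from 0.32 to 0.51, highest on the M202 6-day array, and that of ubiquitin from -0.42 to -0.08, lowest on the M202(Sub1) 6-day array. Signal at the 18S ribosomal RNA control was lower at 6 days, with differences of -1.12 in M202 and -0.68 in M202(Sub1), and the ribosomal protein list was lower on the same arrays, with medians of -0.65 and -0.36. At 1 day ribosomal RNA signal was also lower in M202(Sub1) than in M202, with differences of -0.85 at 18S, -0.59 at 28S and -0.46 at 25S. At 6 days these were -0.42, -0.09 and 0.12. The bacterial spike control BioB was higher in M202(Sub1) by 0.21 at 1 day and 0.30 at 6 days. The latter was about as large as the genotype median of the ribosomal protein list at 6 days (0.29). Of marker genes for other tissues, the 4 seed storage genes above the floor had genotype medians of 0.08 and 0.04 at 1 and 6 days, the 3 root genes 0.05 and -0.12, and the 1 pollen gene lay at -0.13 at 6 days. The root genes had a median of -0.67 for time in M202 and -0.16 in M202(Sub1).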

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

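The tests of the blast fungus and of probe mismatch on chromosome 6 were chosen after the values they measure had been seen, as were the demands that the fungal probe sets lie well above the floor and that OSH1 not oppose the meristem markers. The differences between single arrays in this part were not tested, since each group is 1 array. The additive model tested genotype only over both times together.

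Among named genes, CPS2 (-4.11), NAS1 (-4.18), CYP71Z7 (-3.57) and DREB1B (2.89) had genotype differences of at least 2-fold in opposite directions at 1 and 6 days, and GER2 (-2.86) had time differences of at least 2-fold in opposite directions in the genotypes, the values being the difference between the time differences. PBZ1 (-4.19) and OSH1 (4.23) met both descriptions. Both 1-day values of CPS2, and 1 value at each time of NAS1 and of OSH1, lay under the floor, so these 3 reversals are uncertain. Among all genes, 8 were at least 2-fold higher in M202(Sub1) at 1 day and at least 2-fold lower at 6 days, and 13 were the other way round. Of the lists, diterpenoid phytoalexins alone lay outside the random range in opposite directions at the 2 times, with a difference of -1.87. At 1 day CPS2 and CYP76M7 of this list lay under the floor in both genotypes, so its 1-day median rests in part on signal near background.

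The phytoalexin genes were lower in M202(Sub1) than in M202 at 6 days by a median of -1.29. The median was -1.32 after quantile normalization and -1.32 after median centring, both at percentile 0. RMA had already brought the arrays close to a common distribution, so these settings could move the median little. They do not decide whether scaling of the arrays contributed. Reading of related genes is argued against as far as probe set names mark it, because the median was -1.54 at percentile 0 without those sets. Infection of the M202 plants by the blast fungus stays open, since the 10 Magnaporthe control probe sets differed by 0.10 in the direction opposite to infection of M202 but lay near the level floor, where a light infection or another organism could be missed. Genotype is a biological explanation, and 1 array per group leaves it untested at 6 days. Over both times the additive model called no phytoalexin gene for genotype. It takes a genotype difference that changes between the times as residual, so this does not decide the question.

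Cell cycle and histone genes were higher in M202(Sub1) at 6 days by a median of 0.85. The medians were 0.79 after quantile normalization and 0.82 after median centring, both at percentile 100. Since the deposited values already shared nearly the same distribution, this does not decide whether scaling contributed. A larger share of shoot meristem in that sample may contribute, and of 7 meristem regulators the 3 above the floor had a median of -0.14 (range -0.24 to -0.12), which by the bound set in advance speaks against it. That bound was set aside after the values were seen, because OSH1 (1.88 at 6 days, under the floor in M202) and OSH71 (1.81, under the floor in both) went the other way. Apart from FON1 (-0.12), the markers on both sides lay near background, WOX4 at 5.49 and 5.35 on the 6-day arrays. Tissue makeup thus stays open and cannot be told apart from an effect of genotype, which was not tested at 6 days alone.

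Genes with a genotype difference at both times were grouped on chromosome 6, with 13 in the densest window and 17 when it took 100 genes on either side. A poor match of the donor allele to the probes lowers signal, so it is argued against for the 3 genes of the window that were at least 2-fold higher in M202(Sub1). Other differences in probe match between the alleles were not examined for them. For the 10 lower genes it cannot be told apart from lower expression, since 7 of them lay under the floor on both M202(Sub1) arrays and no sequence was used here. A donor segment on this chromosome is a candidate explanation that these values do not test.

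Probe sets not assigned to exactly 1 gene were outside the comparisons, and 82 of them were at least 2-fold apart in the same direction at both times, 49 higher and 33 lower in M202(Sub1). Of the higher ones, 1 had values of 6.96 and 4.86 on the M202 arrays at 1 and 6 days and 14.39 and 13.72 on the M202(Sub1) arrays, and of the lower ones 1 had 12.33 and 12.36 against 4.80 and 4.47.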

How the results depend on the processing

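The 3 other settings of the chromosome scan were chosen after seeing the data. No paired analysis was possible because each group holds 1 array, so no replicate numbers pair the arrays beyond genotype and time, and the additive model of the report already takes time as a block for genotype. No array could be left out and no other splits were drawn, and the number of arrays and signal near background limit all values. Outside the 4-fold threshold, all 35 alternative counts of 2-fold genes stayed within 1.5 times the main count, and the 14 alternative correlations stayed within 0.05. At 4-fold, the counts were 47 (genotype, 1 day), 132 (genotype, 6 days), 517 (time, M202), 423 (time, M202(Sub1)) and 108 (difference of time differences), fewer by construction. The share of higher genes was then 59.6% for genotype at 1 day and 64.4% for time in M202, both on the other side of an even split, and 79.9% for time in M202(Sub1). Median centring gave 50.9% for time in M202, and the cause of these changes was not tested. The genotype count of the additive test was 0 with the 25th percentile floor, with no floor and without the trend, 2 with the 70th percentile floor, 4 without possibly cross-hybridising sets, 4 with median centring, 11 with quantile normalization and 5 at an adjusted threshold of 0.1. The time count was 1428 without the trend and 5021 at 0.1. Of 59 list medians outside their random range, 43 stayed outside under each alternative that left at least 4 genes and 16 did not in some, among them jasmonate and trehalose. Starch breakdown at 1 day reversed, from -0.29 to 0.0187 with the 25th percentile floor, and the fermentation list held 3 genes at the 70th percentile floor, so it got no percentile there. Of 956 values of named genes, each in a difference for which the rule took the gene, 27 moved and none of at least 2-fold changed sign. Outside these, the 1-day genotype difference of NSHB1 went from 1.86 to -0.29 without possibly cross-hybridising sets. The window on chromosome 6 held 8 genes with 25 genes on either side. The count around SUB1C was not run.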

Other observations

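The trehalose phosphatase gene OsTPP1 went from 8.23 to 9.14 in M202 and from 9.14 to 11.58 in M202(Sub1), and the 5 trehalose phosphatase genes had a median time difference of -0.02 in M202 and 0.58 in M202(Sub1). The latter came to 0.37 with the 25th percentile floor or without possibly cross-hybridising probe sets and to 0.15 with no floor, each inside the random range. Their genotype median at 6 days was 0.56, and 0.11 to 0.32 under the same 3 alternatives, inside the random range. ABA8OX1 was at 11.68 in M202(Sub1) and 8.98 in M202 at 6 days, while the dehydrin RAB21 was lower in M202(Sub1) at both times. The 11 abscisic acid and dehydration genes had a genotype median of 0.07 at 6 days, inside the random range. They had a median time difference of 0.44 in M202(Sub1) and 0.18 in M202, and 0.25 in M202(Sub1) without possibly cross-hybridising probe sets, inside the random range. The phosphate starvation list had medians of 0.38 and 0.17, with SPX5 at 1.69 and 0.17.

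NAS1 was higher in M202(Sub1) at 1 day (7.06 against 5.51) and lower at 6 days (3.36 against 5.99). NAAT1, a nicotianamine aminotransferase, rose with time by 3.15. Sugar transporter genes were lower in M202(Sub1) at both times, with medians of -0.22 and -0.24, the second inside the random range at -0.15 with the 25th percentile floor, -0.13 with no floor and -0.15 with the mean of all probe sets, and SWEET14 was at -1.12 at 6 days. The 48 auxin response genes had a median of 0.16 at 6 days. Ethylene synthesis and signalling, gibberellin and brassinosteroid genes had genotype medians at 6 days of 0.03, 0.10 and 0.05, inside the random range. At 1 day, gibberellin genes (0.13) lay outside it in 2 alternatives and brassinosteroid genes (-0.19) in 1, and gibberellin genes did so for time in M202(Sub1) (-0.33) in 2.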
